A study of Mus musculus with 4 samples.

How the data were processed

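RNA from the intestinal epithelium of adult C57BL/6 mice was crosslinked to protein with ultraviolet light, immunoprecipitated and read on Affymetrix Mouse Gene 1.0 ST arrays, an approach known as CLIP-chip. The 4 groups were input RNA, IgG control, Msi1 antibody and hnRNP antibody, with 1 array each, and every array carried RNA pooled from 2 independent experiments, with 100 ng labelled. Groups were taken from the antibody named in the sample labels. The log2 values are used as deposited by the authors, 1 summarized value per probe set and array. The submitters' processing notes name the tool affy without a version, and the background correction, normalization and log base are not given in the sources used here. Base 2 was inferred from the range of the values, 1.07 to 14.3, so every log2 difference and fold rests on that reading. The arrays' distributions differed, with a standard deviation across all probe sets of 2.01 for input, 1.17 for IgG, 1.38 for Msi1 and 1.20 for hnRNP. The values had thus not been quantile normalized at this level, and a scaling that assumes equal distributions could change any difference.

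Of 34760 probe sets, 21640 carried 1 gene symbol and were used for 19937 genes. A further 1321 carried several symbols and 11799 had no symbol here, and both kinds were kept for the closing section. Entrez identifiers matched 21553 probe sets to the RefSeq gene table. For the 954 genes with more than 1 probe set, the one with the highest mean over the 4 arrays was taken. Each array's detection floor was the 95th percentile of 1206 olfactory and vomeronasal receptor probe sets (1192 genes), which gut epithelium should not express. The floors were 4.09 for input, 5.26 for IgG, 4.74 for Msi1 and 5.17 for hnRNP. On arrays, the signal over this floor takes the place of depth, and 13591 genes exceeded it on at least 1 array.

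For each of 6 comparisons the difference of the log2 values was taken for genes above the floor on at least 1 of the arrays compared, and genes at least 2-fold higher or lower were counted. No p-values were computed, since 1 array per group gives no measure of spread. Where the dimmer value was below its floor, a fold is given as a lower bound against the floor. The comparisons, the floor, the gene lists and the rule for naming genes were fixed before the data were examined. Genes named are the 15 highest and 10 lowest in Msi1 against IgG, the 8 highest and 5 lowest in the other comparisons, Msi1, Msi2 and published Musashi targets, up to 4 members of each list, and the 15 genes with the largest excess in Msi1 over all other arrays. Symbols of predicted genes, clones, microRNAs, receptors and small nucleolar RNAs named Snora or Snord were left out of the rankings and described as groups, while the related Scarna symbols were ranked. Ranks follow the deposited values, so where the dimmer value is below its floor a gene's rank depends in part on background.

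In total 33 gene lists were fixed. They covered Musashi targets, the Musashi and hnRNP family, Wnt, Notch and PI3K and mTOR pathways, proliferation, markers of stem cells, enterocytes, Paneth, goblet, enteroendocrine and tuft cells, markers of immune cells, stroma and muscle, and enteric neurons and glia, and general, noncoding and structural gene families. The receptors define the floor and were not tested. Mitochondrially encoded genes and red blood cell genes had fewer than 5 detected members and were not tested, which left 30. Of 376 members sought by symbol, 44 were not found. A list's median difference over members detected on at least 1 array was placed among 10000 random lists of the same size matched on mean signal in 20 bins, and a list stood apart at a percentile under 2.5 or over 97.5. This percentile describes these arrays and is not a test across animals.

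The overlap of the genes higher with both antibodies over IgG was set beside independence and beside 100 simulations of unchanged arrays that shared the control. Correlations were computed across genes. The steps were tested on simulated data with a noise standard deviation of 0.43 and no offset between arrays. This noise was taken from the receptor genes, most of which lay below the floor. Of genes raised by 2 log2 units, 98% were called, of unchanged genes 5.08% were called higher, and 2.5% of unshifted lists stood apart. These rates describe the simulation and may not hold here, where 0.839% of receptor genes were higher and 16.2% lower in Msi1 than in IgG. Alternatives were median centring, quantile normalization, loess centring with a span of 0.4, a floor at the 99th percentile or none, detection on both arrays, thresholds of 1.5-fold and 3-fold, the mean of a gene's probe sets, the probe set brightest on input, and other matchings and members of the lists, among them lists without members that share only the start of a symbol. Computations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. A planned count of the UAG motif, the core of Musashi binding sites, in 3′ untranslated regions was not run because no genome sequence was used here.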

Results

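The data set held 4 microarrays of RNA from the intestinal epithelium of adult C57BL/6 mice in which RNA and protein had been crosslinked with ultraviolet light. RNA was immunoprecipitated with an antibody to Musashi1 (Msi1), an RNA-binding protein of progenitor cells in the gut and nervous system, or with an antibody to a heterogeneous nuclear ribonucleoprotein (hnRNP), a class of abundant nuclear RNA-binding proteins. Which hnRNP was targeted is not given in the sources used here. A nonspecific IgG precipitation was the control, and input RNA was the starting material. Each of the 4 groups had 1 array, made from RNA pooled from 2 experiments, so there were no replicates. The number of arrays limits the precision of every value, and differences were described by size and not tested. Values were log2 signals that ranged from 1.07 to 14.3.

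The input array was the one on which the most genes stood above background. Of 19937 genes measured, 11783 (59.1%) exceeded the input array's detection floor, which was set by olfactory and vomeronasal receptor genes. The Msi1 array had 9519 such genes (47.7%), the hnRNP array 6555 (32.9%) and the IgG array 5604 (28.1%). Median signals over all probe sets were 4.27 on the input, 4.66 on the IgG, 4.53 on the Msi1 and 4.65 on the hnRNP array. Across genes, which are not independent replicates, the Msi1 array correlated with input at Pearson's r = 0.740 (Spearman's rho 0.766). IgG and hnRNP correlated with input at r = 0.422 and 0.421 (rho 0.453 and 0.462) and with each other at r = 0.794 (rho 0.766). Msi1 correlated with IgG at r = 0.615 (rho 0.641) and with hnRNP at r = 0.622 (rho 0.654).

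Msi1 was compared with IgG to rank transcripts by their enrichment over the control precipitation. Calm2, a calmodulin gene, was at least 50.7-fold higher in Msi1 and was past 2-fold on both of its probe sets, with differences of 4.58 and 6.03 log2 units. Cdkn1b, which encodes the cyclin-dependent kinase inhibitor p27, was 45.8-fold higher (5.52 log2 units) on the probe set with the higher mean over the 4 arrays. It differed by 0.59 on its other probe set. The first was above the floor on both arrays, but its IgG value of 5.38 lay near the floor of 5.26. It was also the dimmer of the 2 on IgG (5.65 for the other) and on input (4.37 against 6.89). Ppp4r2, a regulatory subunit of protein phosphatase 4, was at least 28.1-fold higher, and Tox4, which encodes an HMG-box protein, at least 23.5-fold. Their deposited values differed by 7.05 and 7.79, but their IgG values of 3.03 and 2.03 lay below the floor. In all, 1927 of 10363 genes (18.6%) were at least 2-fold higher in Msi1 than in IgG and 716 (6.91%) were at least 2-fold lower.

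The remaining genes of the 15 with the largest excess over IgG had several roles. Sptssa, a subunit of the enzyme that starts sphingolipid synthesis, differed by 6.17 (at least 24.6-fold). The histone gene H2bc4 differed by 5.65 (at least 14.6-fold) and the Golgi nucleotide sugar transporter Slc35a3 by 5.27 (at least 12.3-fold). Gas5, a noncoding host gene of small nucleolar RNAs, differed by 5.38 (at least 15.3-fold), and 2 of its 4 probe sets were past 2-fold. Nus1, which takes part in dolichol synthesis, was at least 19.8-fold higher, and Pcnp, which encodes a nuclear protein, at least 26.0-fold. The transmembrane protein gene Tm9sf3 was at least 18.3-fold higher and Hnrnpc, an hnRNP gene, at least 13.7-fold. Dstn, which encodes the actin-depolymerizing protein destrin, was at least 25.9-fold higher. Pnrc2, a nuclear receptor coactivator gene, and Mal2, which acts in transcytosis, were at least 19.0-fold and 20.8-fold higher.

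Among the 10 genes furthest below IgG, Ftl1, the ferritin light chain, was 5.70-fold lower (−2.51) and the immunoglobulin kappa gene Igkv4-55 was 4.58-fold lower (−2.20). Cd79a, a part of the B cell receptor, was at least 2.20-fold lower (−2.77). Cyb5d1 (−2.76) was at least 5.31-fold lower on 1 probe set and differed by −0.03 on the other, and Kcnj14, a potassium channel gene, was at least 4.39-fold lower (−2.54). Mrps10, a mitochondrial ribosomal protein gene, was at least 2.39-fold lower, Wfikkn1 at least 2.69-fold and the gamma-tubulin gene Tubg2 at least 3.11-fold. Fbxl7 and Mrgpra6 were at least 1.83-fold and 1.60-fold lower, which is under 2-fold once the dimmer value is raised to the floor.

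The IgG value lay below its floor for 1552 of the 1927 higher genes, so their folds are lower bounds. With the dimmer value raised to the floor, 1118 genes were at least 2-fold higher and 401 lower. Of the receptor genes, 0.839% were at least 2-fold higher and 16.2% at least 2-fold lower, with a median of −0.39. Receptor shares here and below are over all 1192 receptor genes, without the floor that other genes had to pass. Of all genes called, 72.9% were higher. This share depended on the floor. It was 54.8% without a floor (1992 higher and 1644 lower) and 59.6% with detection on both arrays (375 and 254). With the floor at the 99th percentile it was 83.8% (1708 and 329). Median centring gave 81.1% and loess centring 75.9%. Quantile normalization gave 2311 higher and 1582 lower genes, so that 59.4% were higher. The median of all genes moved by 0.13 when each array was centred on its median and by 0.18 with loess centring, and 1832 of the 1927 genes remained at least 2-fold higher with quantile normalization and 1866 with loess centring.

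**Figure D1:**
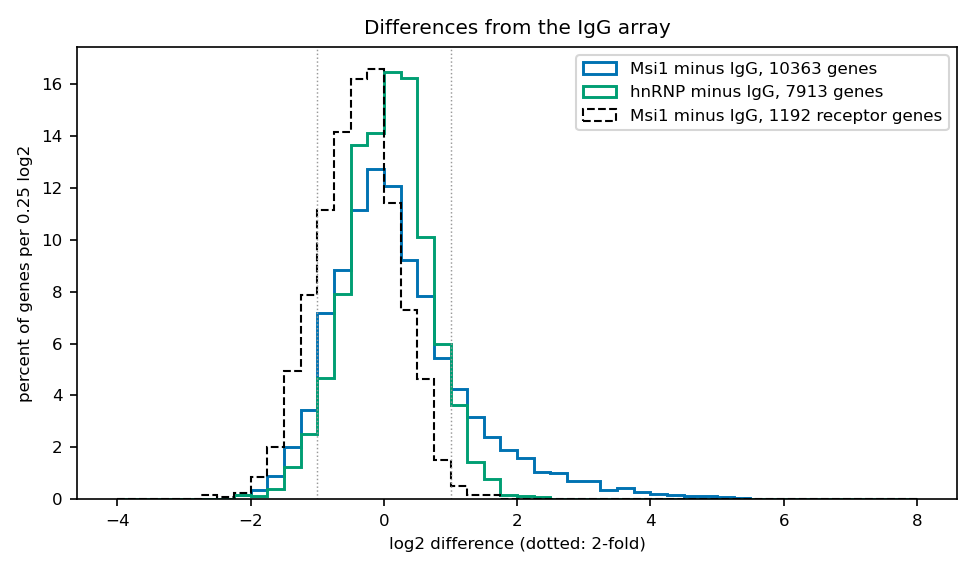
Distribution of log2 differences from the IgG array, as the percent of genes in each bin 0.25 log2 units wide, for Msi1 (10363 genes), hnRNP (7913 genes) and the receptor genes in Msi1 (1192 genes, dashed). The Msi1 distribution has a long right side, with 18.6% of genes past 2-fold (dotted line), against 6.27% for hnRNP and 0.839% for the receptor genes. All receptor genes are counted, most of them below the floor that the other genes had to pass. Their share is thus not a background rate for the others.

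Msi1 was also compared with the other 3 arrays together, and 128 genes were at least 2-fold higher in Msi1 than in each of IgG, input and hnRNP. Cdkn1b led them, with signals of 10.90 in Msi1, 4.37 in input, 5.38 in IgG and 5.44 in hnRNP, and was 92.3-fold higher in Msi1 than in input. Its values on these other 3 arrays lay near their floors of 4.09, 5.26 and 5.17, so its folds rest on values near background. Sptssa exceeded input by 4.09, IgG by 6.17 and hnRNP by 6.43. Cflar, an inhibitor of caspase activation by death receptors, exceeded input by 3.52 and IgG by 4.76. Its excess over input was 0.58 with the mean of its probe sets. It was 0.04 with quantile normalization, where the probe set was chosen again, so this value does not measure scaling alone. As deposited, the other Cflar probe sets differed from input by −1.27 and −0.52. Snrpe, a core protein of spliceosomal particles, exceeded input by 3.12, and Pawr, a gene that promotes apoptosis, by 2.91. Others among the 15 with the largest excess were Pdcd10 (2.86 over input), the TFIID subunit gene Taf13 (2.85), Fam136a (2.70), Ppp4r2 (2.66), Selenok (2.57), Dcun1d1, which acts in neddylation (2.48), Erh (2.44), Calm2 (2.41) and Fahd1 (2.30). The tubulin cofactor gene Tbca, also among the 15, exceeded IgG by 3.66 and hnRNP by 4.28. Selenok, an endoplasmic reticulum selenoprotein gene, was below the floor in input.

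Of the 128 genes, 120 were above the floor in input and 109 were at least 2-fold over the floor of every array. Of the 1927 genes higher than IgG, 157 were also at least 2-fold higher than input, 898 were at least 2-fold lower than input and 872 were neither. The count was 333 with quantile normalization, 614 with loess centring and 21 with genes above the floor on all arrays. Several of the leading genes rested on 1 of their probe sets, and taking the probe set with the highest mean over the 4 arrays favours those that are bright in Msi1. Only 34 of the 128 genes had more than 1 probe set, so the others could not change with the choice of probe set. With the probe set brightest on input, 112 of the 128 genes stayed in the group, and Cdkn1b, Cflar, Erh and Taf13 were among those that left it. The second Cdkn1b probe set differed from IgG by 0.59 and from input by −0.64. The other Cflar probe sets differed from IgG by −0.14 and 0.45, the second of Pdcd10 by 0.58 and that of Taf13 by 0.07.

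**Figure D2:**
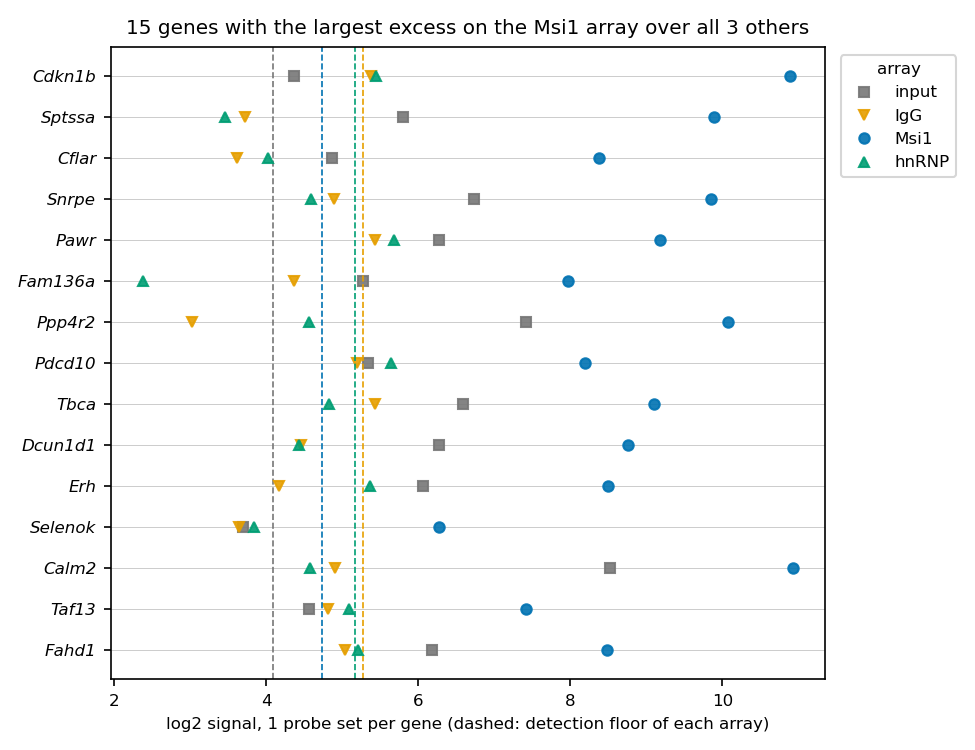
Log2 signal (horizontal axis) of the 15 genes with the largest excess on the Msi1 array over the input, IgG and hnRNP arrays, 1 symbol per array, with each array's detection floor dashed. Cdkn1b reads 10.90 in Msi1 and at most 5.44 in the other arrays, and Calm2 is the brightest on the input array at 8.52.

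Published Musashi target genes did not shift as a group against IgG, but 6 of the 21 detected were at least 2-fold higher in Msi1 and 0 were lower. Beside Cdkn1b, on 1 probe set, these were the TGF-beta receptor Tgfbr1 (2.92, at least 2.14-fold), the BMP receptor Bmpr1a (2.69, at least 3.30-fold) and the Notch inhibitor Numb (2.57, at least 2.58-fold). Tspan3, a tetraspanin, differed by 2.28 (at least 3.57-fold) and Apc, a brake on Wnt signalling, by 1.16, or 0.82 with the IgG value raised to the floor. The cyclin Ccnd1 differed by 0.65, the Notch ligand Jag1 by 0.63, Msi2 by 0.64, Ptprf by 0.12 and Notch1 by −0.22. The stem cell regulator Lrig1 differed by −0.23, Cdk6 by −0.36, Myc by −0.50, Numbl by −0.55, Smad3 by −0.59, Ikzf2 by −0.81 and Robo3 by −0.96, and with quantile normalization the last 2 were past 2-fold lower (−1.04 and −1.17). The median of the group was −0.04, at percentile 28.8 of random gene lists of the same size and signal level. Msi1 itself read 12.16 in input, 8.14 in IgG, 8.09 in Msi1 and 6.07 in hnRNP, and Msi2 read 6.17, 5.93, 6.57 and 6.20.

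Of the 30 gene groups tested against IgG, 4 stood apart from random lists as higher in Msi1 and 1 as lower, and these 5 medians kept their sign with quantile normalization and loess centring. Musashi and hnRNP family genes had a median difference of 1.71 (percentile 99.99), with 14 of 23 at least 2-fold higher and 1 lower. Hnrnpc (5.20) and Hnrnpa2b1 (4.57, at least 11.6-fold) were the highest and Hnrnph2 (−1.01) and the splicing regulator Ptbp1 (−0.73) the lowest. Absorptive enterocyte markers had a median of 1.43 (percentile 99.5), with 15 of 24 higher and 0 lower. Fabp2, a fatty acid-binding protein, was at least 22.9-fold higher and the peptidase Dpp4 at least 4.93-fold, and the sugar-handling genes Slc2a5 and Treh differed by −0.80 and −0.69. PI3K and mTOR pathway genes had a median of 0.55 (percentile 97.8), with 6 of 18 higher, among them the mTOR inhibitor Ddit4 (1.97, at least 1.67-fold) and Pik3r1 (1.76, at least 1.94-fold), while Eif4ebp2 differed by −0.61 and Mtor by −0.13. Small nucleolar RNAs had a median of 0.46 (percentile 99.9), with 10 of 43 higher, such as Snora23 (3.34, at least 4.80-fold). MicroRNA genes had a median of −0.29 (percentile 0.04), with 13 of 97 lower, such as Mir713 (−1.63, at least 1.86-fold) and Mir196b (−1.51, at least 1.69-fold), and 3 higher, led by Mir692-1 (1.61, 3.06-fold). With random lists matched on the input level, the percentiles were 91.9 for enterocyte markers, 88.5 for PI3K and mTOR pathway genes, 93.5 for small nucleolar RNAs and 20.2 for microRNA genes, and Musashi and hnRNP family genes detected on all 4 arrays were at percentile 84.9.

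The other epithelial groups did not stand apart from random lists in Msi1 against IgG. Goblet cell markers had a median of 1.04 (percentile 96.3), with 7 of 13 higher, including the mucus protein Zg16 (4.70-fold) and Ccl6 (at least 2.02-fold), and the goblet cell transcription factor Spdef 2.88-fold lower, and with quantile normalization the group stood apart as higher (percentile 98.4). Paneth cell markers had a median of 0.40 (percentile 62.4), with 3 of 9 higher, including the antimicrobial lectin Reg3g (5.50-fold) and Guca2b (at least 2.99-fold). Intestinal stem cell markers had a median of −0.10 (percentile 30.6), with Olfm4 at least 6.72-fold and Slc12a2 at least 2.99-fold higher and the ephrin receptor Ephb3 at least 1.89-fold lower. Wnt pathway genes had a median of −0.12 (percentile 13.9), with 6 of 22 higher, led by the kinase Csnk1a1 (at least 8.78-fold) and the cyclin Ccnd2 (6.09-fold), and 1 lower, Dkk3. Notch pathway genes had a median of −0.07 (percentile 40), with 4 of 18 higher, including Numb and the protease Adam10 (2.31, at least 2.02-fold). Proliferation genes had a median of −0.12 (percentile 20.6), with 3 of 23 higher, including the replication clamp Pcna (4.49, at least 14.5-fold) and Top2a (1.69, at least 2.40-fold), and Plk1 lower (−1.13), and stood apart as lower with lists matched on input (percentile 0.99). Enteroendocrine markers had a median of 0.04 (percentile 64.4), with 1 of 19 lower, Chga (−1.43, at least 1.79-fold). Tuft cell markers had a median of −0.29 (percentile 24.4), with Rgs13 higher (2.60, at least 2.26-fold) and 2 of 12 lower, including Ltc4s (−1.40, at least 2.41-fold). Keratin and claudin genes had a median of −0.22 (percentile 12.3), with 4 of 37 higher, including Krt20 (3.46, 11.0-fold), and 3 lower. Solute carrier genes had a median of −0.02 (percentile 56.3), with 40 of 264 higher and 11 lower.

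Markers of other cell types did not stand apart, except immunoglobulin genes once a misplaced member was left out. Immune cell markers had a median of −0.25 (percentile 16.6), with 1 of 16 lower. The immunoglobulin list had a median of −0.59 (percentile 5.42), with 3 of 7 lower, but 1 of the 7 was the helicase gene Ighmbp2, taken in by the start of its symbol. Without it, a choice made after its value was seen, the 6 immunoglobulin genes detected had a median of −0.82 and stood apart as lower (percentile 1.12), as did all 11 on the array (−1.05, percentile 0). Stromal and muscle markers had a median of −0.19 (percentile 30.2), with 0 of 13 higher or lower. Enteric neuron and glia markers had a median of −0.44 (percentile 12.1), with 2 of 10 lower.

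Genes of general cell functions did not stand apart as groups either, though single members were far above IgG. Cytosolic ribosomal protein genes had a median of 0.53 (percentile 74.0), with 18 of 58 higher, including Rps7 (at least 10.5-fold) and Rps6 (11.2-fold), and 5 lower, including Rplp2 (−1.97) and Rpl9 (−1.82). The Rpl9 value in Msi1 (4.60) lay below the floor of 4.74, and its other probe sets differed from IgG by −1.53 to 1.49. Mitochondrial ribosomal protein genes had a median of 0.11 (percentile 68.5), with 13 of 74 higher and 5 lower. Nuclear-encoded oxidative phosphorylation genes had a median of 0.14 (percentile 18.9), with 19 of 75 higher, including Cox7b (26.2-fold) and Atp5g3 (at least 11.7-fold), and 4 lower, including Ndufb7 (−1.53) and Ndufs5 (−1.46), and were at percentile 0.15 with lists matched on input. Translation initiation and elongation factors had a median of 0.14 (percentile 63.3), with 17 of 56 higher, including Eif3e (at least 8.75-fold) and Eif4g2 (at least 8.55-fold), and 1 lower, and stood apart as higher with quantile normalization (percentile 98.6). Without 11 kinases, methyltransferases and binding proteins of these factors, which the list took in by their symbols, the other 45 had a median of 0.45 (percentile 96.5). Of 13 housekeeping genes (percentile 88.1), 9 were higher, including B2m (15.4-fold) and Hprt (at least 2.82-fold). Immediate early and stress genes had a median of 0.15 (percentile 35.5), with 3 of 19 higher, led by the chaperone Hsp90aa1 (at least 11.2-fold). Replication-dependent histones had a median of −0.13 (percentile 11.2), with 2 of 22 higher and 3 lower, and stood apart as lower with members detected on all 4 arrays (percentile 2.44). Nuclear long noncoding RNAs had a median of −0.08 (percentile 40.3), with Gas5 and Malat1 (14.2-fold) higher among 5. Small nuclear and structural RNAs had a median of 1.17 (percentile 80.1), with 4 of 8 higher, including the Y RNA Rny3 (11.7-fold), and stood apart as higher with all members (percentile 97.8). Zinc finger protein genes had a median of −0.10 (percentile 42.5), with 25 of 249 higher and 20 lower, and stood above random lists with all members (percentile 98.6, median −0.15).

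**Figure D3:**
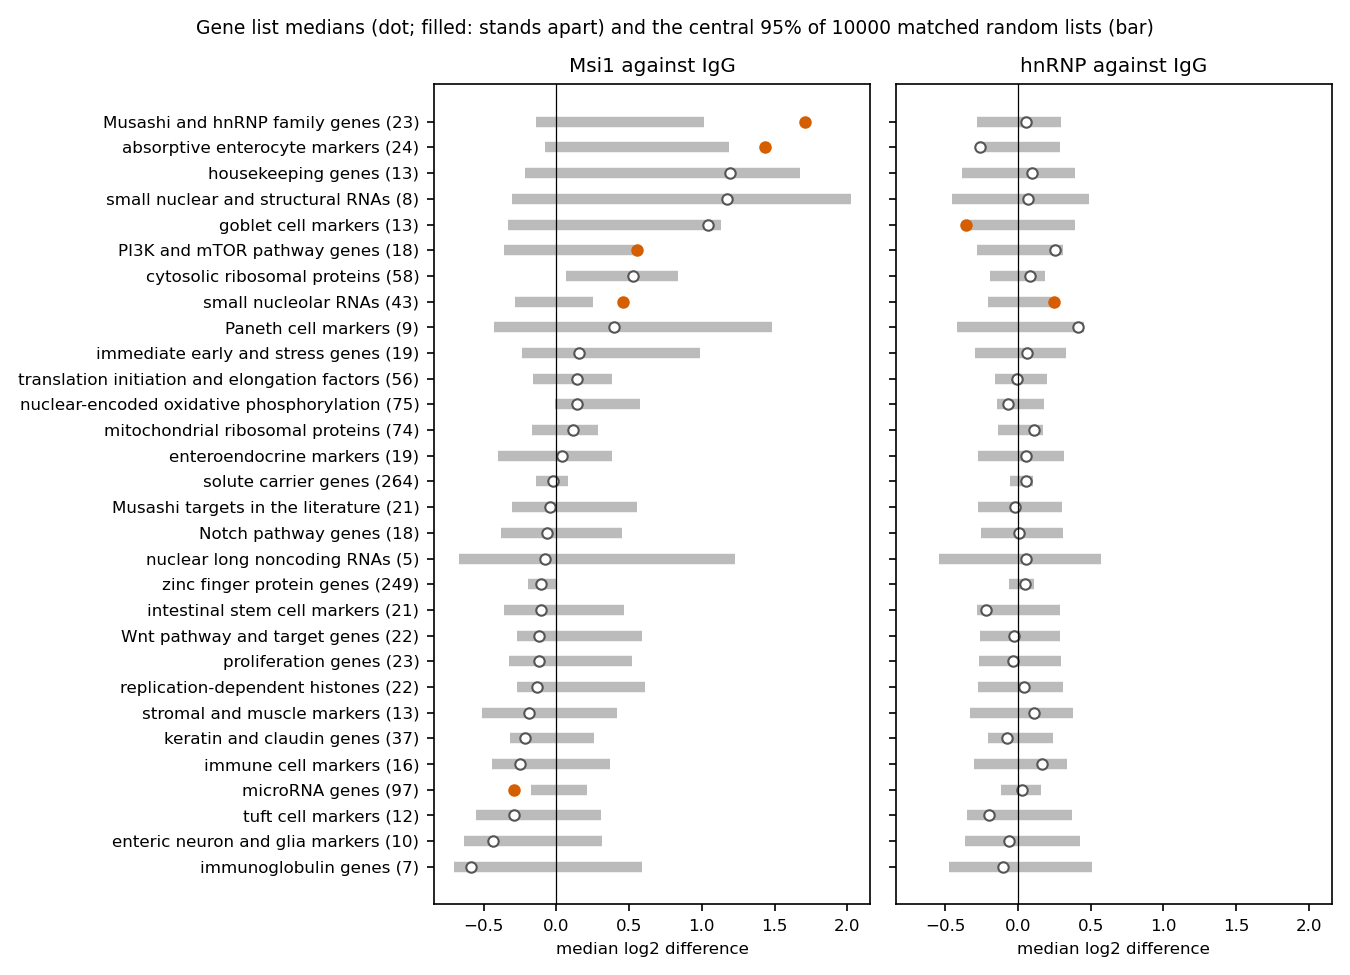
Median log2 difference of each gene group (dot, number of genes in brackets) in Msi1 against IgG and in hnRNP against IgG, with the central 95% of 10000 random lists matched on signal level (bar) and filled dots where the median falls outside it. Musashi and hnRNP family genes lie at 1.71 in Msi1 and at 0.06 in hnRNP, and absorptive enterocyte markers at 1.43 and −0.26.

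The hnRNP antibody was compared with IgG in the same way. Scarna17, a small RNA of Cajal bodies that was also counted among the small nucleolar RNAs, was 33.9-fold higher in hnRNP than in IgG (5.08), and Rbm25, a splicing regulator, was at least 9.66-fold higher (3.35), or 0.26 on the probe set brightest on input. Btnl5-ps was 8.52-fold higher on 1 of 3 probe sets (the others 1.04 and −0.45), Frmd6 at least 3.03-fold and Actr3, a part of the actin-nucleating Arp2/3 complex, at least 3.65-fold. Uba1y (2.65), Tfb2m (2.43) and Nsa2 (2.35) were also among the 8 highest, but differed by 0.51, 0.83 and 0.23 with the mean of their probe sets. The lowest was the Paneth cell lysozyme Lyz1, at least 7.66-fold lower (−3.49), followed by the defensin Defa24 (−2.98, at least 3.21-fold), Cbx3 (−2.64, at least 1.24-fold, but −0.45 with the mean of its probe sets), Gdap2 (−2.16, at least 2.13-fold) and Ftl1 (−2.16, 4.47-fold). Of 7913 genes, 496 (6.27%) were at least 2-fold higher and 357 (4.51%) lower. These counts were 135 and 93 with the dimmer value raised to the floor, but 1017 and 847 with quantile normalization. Of the receptor genes, 5.45% were higher and 8.31% lower.

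Of the 30 groups, 2 stood apart in hnRNP against IgG. Small nucleolar RNAs had a median of 0.25 (percentile 98.3), with 7 of 43 higher, led by Snora3 (at least 9.87-fold) and Scarna17, and 2 lower, and with the mean of probe sets the percentile was 95.8. Goblet cell markers had a median of −0.35 (percentile 2.36), with 3 of 13 lower, including Agr2 (−2.14, at least 1.61-fold) and Zg16 (−1.27, 2.41-fold), and the percentile was 4.46 with lists matched on input and 3.10 with loess centring. Absorptive enterocyte markers had a median of −0.26 (percentile 3.36), with 4 of 24 lower, including the disaccharidase Mgam (−1.64, at least 1.62-fold). Paneth cell markers had a median of 0.41 (percentile 96.2) and microRNA genes 0.03 (percentile 51.5). Musashi and hnRNP family genes had a median of 0.06 (percentile 62.3), with 4 of 23 higher and 2 lower, among them Msi1, 4.19-fold lower (−2.07).

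Msi1 was compared with hnRNP to find RNA that differed between the antibodies. Calm2 was at least 54.3-fold higher in Msi1 (6.35), and its second probe set differed by 4.28. Kdm7a, a histone demethylase gene, was at least 37.1-fold higher (7.69) on 1 probe set and differed by 1.65 on the other, with both hnRNP values below the floor. Tox4 (6.75) and Sptssa (6.43) were at least 25.1-fold and 26.3-fold higher. Slc44a1, a choline transporter gene, was at least 18.0-fold higher (2.04 log2 units on its second probe set), H2bc4 at least 15.6-fold, Clec2h at least 35.1-fold and Hnrnpc at least 14.7-fold. Higher in hnRNP were Scarna17 (−2.37, 5.16-fold), Uba1y (−2.44, at least 4.49-fold, but −0.80 with the mean of its probe sets), Zfp213 (−2.25, at least 2.26-fold), Cd79a (−2.27, at least 1.56-fold) and Defb35 (−2.45, at least 1.42-fold). Of 10664 genes, 1862 (17.5%) were at least 2-fold higher in Msi1 and 830 (7.78%) lower, so that 69.2% of these were higher. The split was 2241 and 1682 with quantile normalization (57.1% higher), 2124 and 539 with median centring (79.8%) and 2181 and 542 with loess centring (80.1%). The share higher was 55.5% without a floor, 55.3% with detection on both arrays and 80.1% with the floor at the 99th percentile. With the dimmer value raised to the floor, 1165 were higher and 431 lower. For the receptor genes, the shares were 1.68% higher and 12.1% lower, with a median of −0.32.

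Musashi target genes higher in Msi1 than in hnRNP were Cdkn1b (43.8-fold), Bmpr1a (at least 3.53-fold), Tgfbr1 (at least 2.29-fold), Tspan3 (at least 3.82-fold), Numb (at least 2.77-fold), Apc (at least 1.89-fold) and Msi1 itself (4.05-fold), and Robo3 was lower (−1.15, at least 1.79-fold). Their group median was 0.31 (percentile 90.0). Of the 30 groups, 4 stood apart as higher in Msi1 than in hnRNP. Enterocyte markers had a median of 1.62 (percentile 99.7), with 15 of 24 higher, including Fabp2 and the disaccharidase Sis (3.94, at least 9.03-fold). Musashi and hnRNP family genes had a median of 1.15 (percentile 98.9), with 14 of 23 higher and 2 lower, including Ptbp1 (−1.95, at least 3.59-fold). Translation factors had a median of 0.36 (percentile 98.3), or 0.60 (percentile 99.8) without the 11 regulators, with 19 of 56 higher, including Eif3e (at least 9.36-fold), and small nucleolar RNAs 0.29 (percentile 99.4), with 5 of 43 higher, including Snora23 (at least 5.13-fold), and 3 lower, including Snora3 (6.48-fold). Immune cell markers (−0.58, percentile 0.49) and microRNA genes (−0.41) stood apart as lower, with Cd79b at least 1.91-fold and Mir501 at least 2.48-fold lower. The median of the receptor genes in this comparison was −0.32. With random lists matched on input, 3 of these 6 groups stood apart, and enterocyte markers (percentile 94.0), small nucleolar RNAs (79.4) and translation factors (75.9) did not. With members detected on all 4 arrays, 2 did, enterocyte markers and microRNA genes, while the Musashi and hnRNP family was at percentile 94.7, translation factors at 79.8 and small nucleolar RNAs at 53.5, and immune cell markers had too few members. Small nucleolar RNAs were at percentile 96.5 with quantile normalization, and immune cell markers and microRNA genes at 4.46 and 3.97 with all members.

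Each precipitation was compared with input to set recovered RNA against its source. Against input, Msi1 was highest for Cdkn1b (92.3-fold), Sptssa (17.1-fold), Cflar (11.5-fold), Snrpe (8.69-fold), Psd3 (at least 5.40-fold), Palm3 (at least 5.13-fold), Pawr (7.51-fold) and Pdcd10 (7.27-fold). On the probe set brightest on input, Cdkn1b differed by −0.64, Cflar by −0.52 and Psd3 by −0.65. Msi1 was lowest for the ATP synthase subunit Atp5d (−7.01, 129-fold), the translation factor Eif4a1 (−6.96, 124-fold), Rpl9 (−6.82, its other probe sets from −5.90 to 0.04), Lyz1 (−6.79, 110-fold) and the amine oxidase Aoc1 (−6.66, at least 79.9-fold). Musashi targets lower than input included Msi1 itself (−4.06, 16.7-fold), Ptprf (−2.74), Lrig1 (−2.42), Ccnd1 (−2.32) and Myc (−2.12), of which Ccnd1 and Myc differed by −0.73 and −0.61 with loess centring. Numb (−1.78), Tspan3 (−1.81), Apc (−1.29) and Bmpr1a (−1.10) were also lower, and loess centring turned these 4 to 0.03, 0.12, 0.28 and 0.72. Tgfbr1 (0.46) and Msi2 (0.40) differed little from input, but were past 2-fold higher with loess centring (1.71 and 1.80) and with quantile normalization (1.09 and 1.13). Cdkn2a, a cell cycle inhibitor, was higher (1.46, at least 2.66-fold). Of 12779 genes, 1508 (11.8%) were at least 2-fold higher and 4901 (38.4%) lower, with 23.5% of these higher. The share was 13.3% with median centring (881 and 5729), 39.4% with quantile normalization (1571 and 2414) and 48.0% with loess centring (2225 and 2407). Of the receptor genes, 21.0% were higher and 0.419% lower, with a median of 0.56.

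Of the 30 groups, 10 stood apart as lower and 4 as higher in Msi1 against input. All 24 enterocyte markers were at least 2-fold lower (median −2.94), including lactase, Lct (24.8-fold), and the alkaline phosphatase Alpi (16.5-fold), as were all 9 Paneth cell markers (−3.33). Goblet cell markers (−2.40), with the mucin Muc2 23.9-fold lower, immune cell markers (−1.75), with Cd74 20.2-fold lower, and proliferation genes (−2.03), with 18 of 23 lower, also stood apart. So did oxidative phosphorylation genes (−1.81, 51 of 75 lower, Ndufs7 96.2-fold), small nucleolar RNAs (−1.77, Snord57 at least 48.0-fold), translation factors (−1.46, Eef2 24.1-fold), solute carriers (−1.05, 135 of 264 lower) and housekeeping genes (−2.34). With random lists matched on input, 6 of the 14 calls held, and oxidative phosphorylation genes moved to percentile 77.6, housekeeping genes to 65.0, enteric neuron markers to 72.5, translation factors to 37.7, enterocyte markers to 18.8, goblet cell markers to 9.21, proliferation genes to 2.63 and Paneth cell markers to 2.62. MicroRNA genes (0.82, 41 of 97 higher), stromal and muscle markers (1.13, 8 of 13 higher, Col6a1 4.85-fold), enteric neuron and glia markers (1.05, 5 of 10 higher) and nuclear long noncoding RNAs (1.00, 3 of 5 higher) stood apart as higher. Among the last, Gas5 was 4.51-fold higher on 1 probe set while its others differed by −2.09, −3.04 and 0.12, and the percentile was 82.4 with the mean of probe sets and 96.4 with loess centring.

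The hnRNP precipitation differed more widely from input. Trdn was at least 9.21-fold higher in hnRNP than in input, the heat shock protein gene Hspb1 10.6-fold (1.57 log2 units on its second probe set), Fam43b 9.88-fold, Rbmxl2 9.67-fold, Palm3 at least 7.25-fold, Uba1y at least 7.05-fold and Raet1d at least 3.77-fold. Rpl24 was 11.5-fold higher (3.53) but differed by −0.36 with the mean of its probe sets, and Trdn by 0.09 on the probe set brightest on input. Lyz1 (−9.28, at least 424-fold), Defa24 (−8.20, at least 119-fold), Eif4a1 (−7.77, at least 122-fold), the chaperone Hspa8 (−7.60, at least 138-fold) and Lypd8 (−7.55, 188-fold) were the lowest. Enterocyte (−4.54), Paneth (−4.81), goblet (−3.53) and immune cell markers (−1.73), oxidative phosphorylation genes (−2.62), proliferation genes (−2.16), small nucleolar RNAs (−1.91), solute carriers (−1.28) and translation factors (−2.08) stood apart as lower. MicroRNA genes (1.22), stromal (1.49) and enteric neuron markers (1.34) and keratin and claudin genes (0.68) stood apart as higher. With lists matched on input, 3 of the 13 calls held, and the percentile was 7.50 for goblet and 6.06 for immune cell markers, 91.8 for oxidative phosphorylation genes, 35.8 for enteric neuron and 97.4 for stromal markers, 2.53 for enterocyte markers, 43.3 for proliferation genes, 22.7 for translation factors, 10.04 for small nucleolar RNAs and 90.2 for keratin and claudin genes. Keratin and claudin genes detected on all 4 arrays were at percentile 0.22. Goblet and immune cell markers were at percentiles 4.06 and 4.33 with loess centring. Of 12876 genes, 2402 (18.7%) were at least 2-fold higher and 5579 (43.3%) lower, with 30.1% of these higher. The share was 20.1% with median centring (1639 and 6504), 42.1% with quantile normalization (2924 and 4024) and 48.9% with loess centring (3105 and 3251). Of the receptor genes, 41.9% were higher and 0.252% lower. Their median was 0.88, above that of keratin and claudin genes.

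The IgG control gave the background of the precipitation itself against input. Highest in IgG were Igkv4-55 (12.2-fold), Rpl24 (10.8-fold, with 0.12 as the mean of its probe sets and −1.13 on the one brightest on input), the collagen gene Col6a1 (9.59-fold), Fam43b (9.35-fold), Nphs1 (at least 8.36-fold, but 0.94 on its second probe set), Trdn (at least 6.90-fold, but −0.56 on the probe set brightest on input), Palm3 (at least 6.40-fold) and Zfp382 (at least 4.06-fold). Eif4a1 (−8.20, at least 114-fold), Aoc1 (−7.82), Tm6sf2 (−7.27), the antimicrobial Reg3b (−6.79, at least 47.1-fold) and the intestinal cadherin Cdh17 (−6.67, at least 35.4-fold) were the lowest. Paneth (−5.21), enterocyte (−4.64), goblet (−3.66) and immune cell markers (−1.76), small nucleolar RNAs (−2.27) and solute carriers (−1.40) stood apart as lower. Oxidative phosphorylation genes did too, with 59 of 75 lower, although their median was 0.09 with loess centring and their percentile 99.1 with lists matched on input, where 5 of the 11 calls held. MicroRNA genes (1.23), stromal (1.32) and enteric neuron markers (1.43) and keratin and claudin genes (0.73) stood apart as higher, the last at percentile 0.1 with members detected on all 4 arrays. Matched on input, enteric neuron markers were at percentile 58.0, stromal markers at 93.2, keratin and claudin genes at 96.3, immune cell markers at 5.85 and goblet cell markers at 3.13. Of 12692 genes, 2102 (16.6%) were at least 2-fold higher and 5669 (44.7%) lower, with 27.0% of these higher. The share was 17.7% with median centring (1431 and 6631), 39.4% with quantile normalization (2650 and 4070) and 49.2% with loess centring (3004 and 3105). Of the receptor genes, 47.7% were higher and 0.336% lower, and their median of 0.97 exceeded that of keratin and claudin genes. Median centring moved the median of all genes by −0.25 for Msi1, −0.38 for hnRNP and −0.39 for IgG against input.

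Genes higher over IgG with both antibodies were counted next. Of 7145 genes detected for both, 687 were at least 2-fold higher in Msi1 and 348 in hnRNP, and 140 in both. The shared genes numbered 294 with quantile normalization, 36 with the dimmer value raised to the floor and 23 with detection on all arrays. For the 140, independence gave 33.5 and simulated unchanged arrays that shared the IgG array gave 88.4. The genes lower with both numbered 132, against 88.4 simulated. The simulated noise was taken from the receptor genes, most of which lay below the floor, and no simulated gene was given a true change. The 88.4 is therefore not the sharing to be had from lists of these sizes, and real sharing was not tested. Across genes, the 2 differences from IgG correlated at r = 0.42 (rho 0.49) with a covariance of 0.232, and arrays simulated with no change and a shared control gave r = 0.50 and a covariance of 0.185. Of the pairings that share no array, Msi1 over IgG and hnRNP over input correlated at r = −0.58 (9648 genes, 21 higher in both), and Msi1 over input and hnRNP over IgG at r = 0.05 (7101 genes). No simulated value was computed for these pairings.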

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

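Of the tests in this part, those of array scaling, of how the hnRNP array follows input and of microRNA background were chosen only after the results were seen, and the test of carried-over RNA was set before. Absorptive enterocyte markers had a median difference from IgG of 1.43 in Msi1 and −0.26 in hnRNP. These medians had opposite signs, but the hnRNP median did not stand apart from random lists. Goblet cell markers had medians of 1.04 in Msi1 and −0.35 in hnRNP. MicroRNA genes had medians of −0.29 in Msi1 and 0.027 in hnRNP, the latter at percentile 51.5 of random lists. Directly in Msi1 against hnRNP the medians were 1.62 for enterocyte markers (percentile 99.7 of random lists), 0.97 for goblet cell markers (percentile 96.0) and −0.41 for microRNA genes (percentile 0). These percentiles describe the genes of 1 array per antibody, and a difference between antibodies across animals was not tested. With random lists matched on the input level, enterocyte markers stood apart neither in Msi1 against IgG nor in Msi1 against hnRNP.

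Probe sets that the comparisons left out also passed 2-fold. Of 11799 probe sets without a gene symbol, 1187 (10.1%) were at least 2-fold higher in Msi1 than in IgG and above the Msi1 floor, 1012 were lower, and 290 were higher than on all 3 other arrays. Of 1321 probe sets shared by several genes, 179 (13.6%) were at least 2-fold higher, 80 were lower and 23 were higher than on all 3 other arrays. These shares are over every such probe set, not only those above a floor. By the same rules, 1927 of all 19937 genes were higher in Msi1 than in IgG, and 128 were higher than on all 3 other arrays. Control and intronic probe sets were not told apart from transcripts among those without a symbol, so their counts are not counts of genes.

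The Msi1 array had 3.89 times as many genes at least 2-fold over IgG as the hnRNP array. A difference in scaling or an intensity trend is argued against as the whole account, since the ratio was still 2.27 under the scaling that lowered it most, quantile normalization. Input RNA carried over in proportion to its abundance stays open, because the test set for it cannot decide. Of the 1994 genes in the top 10% of input level, 21.2% read lower in Msi1 than in IgG, more than the limit set beforehand for carry-over. But their differences had a median of 0.79 and a standard deviation of 1.25, and 1 array per antibody does not separate array noise from this spread. At least 2-fold higher were 44.0% of them, against 1.94% of the detected genes below the median input level. Little gut RNA recovered with the hnRNP antibody may contribute, since the hnRNP array followed input no better than IgG did (Spearman's rho higher by 0.00945, against 0.313 for Msi1). Binding of more transcripts by Msi1 stays open as a biological explanation that a single array per antibody leaves untested.

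MicroRNA genes read higher on all 3 precipitation arrays than on input, with medians of 0.82 in Msi1, 1.22 in hnRNP and 1.23 in IgG. Array background where little RNA was hybridized is a candidate explanation, since over all 300 microRNA genes the median of IgG minus input was only 0.270 above that of the receptor genes (1.24 against 0.97). Whether Msi1 retained any microRNA stays open, since in Msi1 against IgG all microRNA genes had a median of −0.37 and the receptor genes −0.39. No biological explanation was tested.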

How the results depend on the processing

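Alternatives added after seeing the data were raising the dimmer value to its floor, taking the probe set brightest on input, leaving out list members that share only the start of a symbol, and the correlation with hnRNP over input. All others were planned. Leaving out replicates was not possible and no paired analysis was possible because there was 1 array per group, and the UAG alternatives were not run without a genome. Of counts and correlations, 110 stayed near the main value, 90 moved and 1 reversed. A count had moved when it changed by more than 1.5 times. A correlation had moved when it left a narrow interval around the main value that treats genes as independent. Of list calls, 227 were the same, 66 weaker and 7 reversed, and of named genes 747 were the same, 34 weaker, 7 stronger and 12 reversed. Signal over background limits the folds, since 1552 of the 1927 genes higher in Msi1 had an IgG value under its floor. Changes with the floor, the detection rule or the threshold follow from how many genes these admit; for the other settings the cause was not tested.

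With median centring, 881 genes were higher in Msi1 than input and 539 lower in Msi1 than hnRNP. With quantile normalization, 1582 were lower in Msi1 than IgG, 2414 lower in Msi1 than input, 1017 higher and 847 lower in hnRNP than IgG, 1682 lower in Msi1 than hnRNP, 333 higher in Msi1 than in all 3 arrays and 294 higher over IgG with both antibodies. With loess centring, 2407 were lower in Msi1 than input, 3251 lower in hnRNP than input, 542 lower in Msi1 than hnRNP, 3105 lower in IgG than input and 614 higher in Msi1 than all 3.

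With the floor at the 99th percentile, 329 were lower in Msi1 than IgG, 723 higher in Msi1 than input, 263 higher and 152 lower in hnRNP than IgG, 1129 higher in hnRNP than input, 414 lower in Msi1 than hnRNP, 889 higher in IgG than input and 70 shared. Without a floor these counts were 1644, 3184, 794, 760, 6134, 1561, 6164 and 214. Detection on both arrays gave 375 higher and 254 lower in Msi1 than IgG, 697 higher in Msi1 than input, 88 and 57 in hnRNP against IgG, 1302 and 1726 in hnRNP against input, 374 and 302 in Msi1 against hnRNP, 1140 and 1507 in IgG against input, 21 higher than all 3 and 23 shared.

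At 1.5-fold, 2972 were higher and 2039 lower in Msi1 than IgG, 2590 higher in Msi1 than input, 1463 and 1123 in hnRNP against IgG, 2830 and 2405 in Msi1 against hnRNP, 284 higher than all 3 and 475 shared. At 3-fold, 1062 and 116 passed in Msi1 against IgG, 364 and 3121 in Msi1 against input, 69 and 47 in hnRNP against IgG, 1219 higher in hnRNP than input, 1104 and 90 in Msi1 against hnRNP, 1108 higher in IgG than input, 47 higher than all 3 and 30 shared. With the dimmer value at its floor, 1118 and 401 passed in Msi1 against IgG, 135 and 93 in hnRNP against IgG, 1165 and 431 in Msi1 against hnRNP, and 36 were shared. Against IgG and hnRNP alone 1451 genes were higher in Msi1, and 21 were shared with hnRNP over input. The correlation of the differences was 0.488 as Spearman's rho and 0.316 without a floor. It reversed to −0.580 with hnRNP over input, a difference that brings in the input level. Msi1 over input and hnRNP over IgG, which share no array either, gave 0.0541.

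Lists apart in Msi1 against IgG numbered 5, and 3 when matched on input (1 of the 5, the Musashi and hnRNP family, with oxidative phosphorylation and proliferation genes now apart as lower), 8 with all members (immunoglobulin genes as lower, small structural RNAs and zinc finger genes as higher beside the 5) and 2 with members detected on all 4 arrays (enterocyte markers and, newly, histones as lower). Without members that share only the start of a symbol there were 6, with immunoglobulin genes as lower beside the 5. In Msi1 against input there were 8 (of 14) with members on all 4 arrays. In hnRNP against IgG, 1 of 2 stood apart when matched on input, with loess centring, all members or the mean of probe sets, and 0 with members on all 4 arrays. In hnRNP against input there were 6 when matched on input and 7 with members on all 4 arrays, in Msi1 against hnRNP 3 and 3, and in IgG against input 17 with quantile normalization and 7 with members on all 4 arrays. Matched on input, the percentile changed sides for enteric neuron and glia markers in hnRNP against input (35.8), for housekeeping genes in Msi1 against input (65.0), and for oxidative phosphorylation genes against input in Msi1 (77.6), hnRNP (91.8) and IgG (99.1). With members on all 4 arrays it did so for keratin and claudin genes against input in hnRNP (0.22) and IgG (0.1). Reversed genes in Msi1 against input were Bmpr1a (0.21 with quantile normalization, 0.72 with loess centring), Apc (0.28), Numb (0.032) and Tspan3 (0.12) with loess centring, and in hnRNP against input Rpl24 (−0.36) with the mean of probe sets. On the probe set brightest on input, Cdkn1b (−0.64), Cflar (−0.52) and Psd3 (−0.65) reversed in Msi1 against input, Rpl24 (−3.00) in hnRNP against input, and Rpl24 (−1.13) and Trdn (−0.56) in IgG against input, since other probe sets were then read.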

Other observations

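Of what this part reports, the scan of symbol families was chosen only after the result was seen, and the tests of the Cdkn1b probe sets were set before. Genes that share a symbol stem and had at least 12 detected members formed 107 families, and in Msi1 against IgG 8 of these stood apart as higher and 5 as lower, where 2.675 would lie beyond each limit among random lists. Timm genes, which import proteins into mitochondria, had a median difference of 0.82, with 6 of 13 at least 2-fold higher and 0 lower, led by Timm21 (at least 11.3-fold), Timm8b (at least 7.09-fold) and Timm17a (at least 3.17-fold). Sorting nexins of the endosome (Snx) had a median of 0.49, with 8 of 28 higher, including Snx13 (at least 11.9-fold) and Snx16 (at least 2.04-fold). Tetraspanins (Tspan) had a median of 0.75, with 4 of 16 higher, including Tspan8 (at least 2.52-fold), and 1 lower. Dnajc cochaperones had a median of 0.46, with 8 of 22 higher, including Dnajc13 (at least 12.1-fold) and Dnajc15 (at least 2.79-fold).

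Sox symbols, 15 transcription factors and the noncoding Sox1ot and Sox6os, had a median of −0.75, with 4 of 17 lower, and the 15 alone −0.75, also with 4 lower. Prss serine proteases had a median of −0.58, with 3 of 25 lower. The receptor genes that set the floor had a median of −0.39 in the same comparison, with 16.2% lower. These 6 families also stood apart when random lists were matched on the input level, and the 7 others did not. Against input the directions were opposite, with Sox symbols at 0.76 (percentile 99.9) and Prss at 0.50 (percentile 98.5) in Msi1, where the receptor genes rose by 0.56, and neither stood apart with lists matched on input. Timm (−0.68), Snx (−0.65), Tspan (−0.82) and Dnajc (−0.50) read lower than input without standing apart, and Timm turned to 0.20 with loess centring, and Snx and Dnajc to 0.16 and 0.40 with loess centring and 0.0074 and 0.07 with quantile normalization. The 7 other families were the proteasome family Psmd (0.67), the kinase family Stk (0.60), the general transcription factors Gtf (0.31), the ubiquitin pathway family Ube (0.48), collagens (−0.48), Wnt ligands (−0.61) and Ccdc genes (−0.28). All 13 medians over IgG kept their sign with median centring, quantile normalization and loess centring.

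The excess of Cdkn1b in Msi1 rested on 1 of its 2 probe sets, with 5.52 against 0.59 log2 units over IgG. Array effects and retention of only parts of transcripts cannot be told apart. Over 461 genes with 2 probe sets above the input floor, the differences between the 2 had a standard deviation of 1.69, which is 1.96 times that of receptor probe sets (0.863), but only 7.21% of these lay above the Msi1 or IgG floor, so they do not measure noise or probe response where there is signal. Of 197 genes called at least 2-fold higher in Msi1 with several probe sets above the input floor, 86 (43.7%) had all of these past 2-fold. The share was 40.7% of 209 when genes were called on the probe set brightest on input. Retention of parts would give such shares, but so could background, so they do not decide. The input floor of 4.09 lies under those of IgG (5.26) and Msi1 (4.74), and dim probe sets could miss 2-fold for that reason alone. In Dnajc13, too, the 15 probe sets varied, with differences from IgG of −0.29 to 4.87. The positions of the probe sets within the transcripts were not used here, and whether the parts retained hold Musashi motifs was not tested.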
